A study of Mus musculus with 16 samples.

How the data were processed

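MicroRNAs were measured in liver of male C3H/HeJ mice, an inbred strain that develops liver tumours readily, in a study of tumours started with the liver carcinogen diethylnitrosamine. Total RNA was extracted with a miRNeasy kit, and 25 ng was end-labelled with pCp-Cy3 and hybridised to one-colour Agilent mouse miRNA arrays, per the labels' protocols. Each of the 16 samples had its own array, and the labels name no pooling. They do not say which controls received the carcinogen. Groups were taken from the sample titles: 7 Ctnnb1-mutated tumours and 3 control livers from mice given phenobarbital, and 3 Ha-ras-mutated tumours and 3 control livers from mice given none. The controls of the last group are called untreated controls, for the missing phenobarbital only.

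The descriptions of the dosing differ. Per the series' design text, the carcinogen was given at 2 weeks or at 6 weeks of age, at 10 or 90 µg per g, followed after 2 weeks by a diet with or without 0.05% phenobarbital for 28 to 36 weeks. Per the labels, the diet lasted 27 weeks, while the labels' treatment protocol gives 28 days of phenobarbital in drinking water. Which dose, age or duration applied to which sample is not settled, and no comparison uses them. They may differ between the arms, and a comparison across arms could not part them from phenobarbital. The labels do not say whether the samples of a group came from separate animals, or whether a tumour and a control shared one. All p-values therefore measure the spread between these samples.

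The spot intensity values were made with Agilent Feature Extraction 10.7.3.1 and its protocol miRNA_107_Sep09, per the file headers. The deposited intensity used here is the software's background-subtracted spot signal, which was not normalised between arrays. Between 37.9% and 48.3% of the spot signals of an array were at or below 0. The deposited table, whose log2 scale was read from its values, holds 147 entries, 146 of them mouse miRNAs, from -1 to 14.88. The submitters' processing notes name R 2.14.1, and the normalisation method is not given in the sources used here. Within each array these values rank as the software's total gene signal does (Spearman's rho across miRNAs 1), and columns share a median of 5.60, except 5.54 for Ctnnb1 tumour replicate 6. Over the 87 entries detected on all arrays, their means rise with the mean log2 total gene signal with a slope of 1.01, as a logarithm of base 2 does. The handling of low values stays unknown, and this table served as an alternative only. Each column matched its own array.

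An array held 12493 spots, of which 11540 were not control spots. They covered 1712 probes, 1672 for 566 mouse miRNAs and 40 for herpesvirus miRNAs. No spot was saturated. Spots the software marked as outliers were left out, spots of a probe were averaged on the linear scale, and control and viral probes were left out. A probe counted as detected where most of its spots were well above background. Signals were divided by the array's 75th percentile over the 117 mouse probes detected on all 16 arrays, since few probes were detected, and multiplied by 1 common constant. They were then raised to a floor of 24.96 (4.64 on the log2 scale), the median over arrays of the lowest detected signal, and taken to log2. A miRNA's value is the mean of its probes. The percentiles before scaling lay between 386 and 1248, and the median spread between spots of a probe on an array was 5.38% to 11.8%. These figures and the number of arrays limit the precision.

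The 96 mouse miRNAs detected on every array of at least 1 group were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, in 1 fit of 4 group means over all 16 arrays. Adjusted p-values are Benjamini-Hochberg values over the 96 miRNAs of a comparison, with a threshold of 0.05. Means are given with the SD and fold changes with the SE of the fit. A miRNA detected on no array of 1 group has only a bound there: the bright group's mean was set against the mean, over the dim group's arrays, of the higher of its own value and the array's lowest detected signal. Many such values equal the floor and have an SD of 0, which lowers the fitted spread and the p-values of these miRNAs. Slide was read from the scanner files. Slide 1 held the 7 Ctnnb1 tumours and 1 Ha-ras tumour; slide 2 held 2 phenobarbital controls, 1 untreated control and 2 Ha-ras tumours; slide 3 held 1 phenobarbital control and 2 untreated controls. No slide held both a Ctnnb1 tumour and a phenobarbital control.

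Before the data were examined, 21 lists of miRNAs (families, genomic clusters, cell-type and pathway groups), the comparisons, their tests and the rule for naming miRNAs were fixed. The rule named, in each of the 3 comparisons with tumours, up to 10 miRNAs with the largest rise and 10 with the largest fall among those called and detected on all arrays of both groups. It added up to 5 bounds in each direction, up to 4 members of each list with the smallest p, and miR-122, miR-21, miR-34a, miR-127, miR-182 and miR-375 always. In the other 2 comparisons it named up to 5 called in each direction, or else the 3 with the smallest p. A miRNA named outside it is said to have been chosen after its values were seen. The 11 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the 55 tests of lists and comparisons. Names are those of the array design. Against a gene table of assembly GRCm38.p6, 94 of the 96 tested miRNAs matched a precursor gene. The array design uses another assembly, so positions are not printed.

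The fit was tested on simulated data made for the 96 miRNAs. Of changes of 0.5 on the log2 scale it recovered 53.1% for the Ctnnb1 comparison, 39.1% for the Ha-ras comparison, 56.3% between the tumours, 39.7% between the controls and 19.7% for the difference of the tumour effects, so that many changes of that size are missed. Of changes of 1 it recovered 92.3%, 83.1%, 90.0%, 80.6% and 66.0% in the same order. The false share among calls was 2.85% to 4.32%. Simulated values were drawn independently, with 1 mean and 1 spread per miRNA, and held no floor and no slide difference. These shares therefore leave out the floor, the slides and the correlation between miRNAs of the real arrays. With no shift, camera at the preset correlation gave p under 0.05 for a list of 7 in 2% to 12% of runs. The 12% was for the Ha-ras comparison. The list was that of the Dlk1-Dio3 imprinted locus, with its members drawn independently. On the real arrays their estimated correlation was 0.64, so these runs do not give the list's error rate there. Alternatives covered the scaling, the background correction, the signal used, the floor, the probe rule and the filter. They also covered array weights, the samples fitted, slide, the replicate number, a fold threshold and each array left out. The scaling over all mouse probes takes the 75th percentile of 1672 probes, of which 137 to 200 were detected on an array. That percentile lies among undetected probes, so this alternative follows signals near background. Quantile scaling was done without the floor, with signals below 1 set to 1 before log2. It thus changes the scaling and the floor together, and its low values follow signals near background.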

Results

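MicroRNAs, short RNAs that repress target transcripts, were compared across 16 liver samples of mice in 4 groups. Ctnnb1 encodes beta-catenin, the transcriptional effector of Wnt signalling, and Ha-ras encodes a small GTPase upstream of the MAP kinases. Phenobarbital is a liver tumour promoter. The groups were 7 Ctnnb1-mutated tumours and 3 control livers of the phenobarbital arm, and 3 Ha-ras-mutated tumours and 3 untreated controls. Between 83 and 117 of 566 mouse miRNAs were detected on an array, and 11.7% to 16.5% of spots were well above background. Correlations between arrays of a group, across miRNAs, were 0.943 to 0.989 for Ctnnb1 tumours, 0.982 to 0.993 for phenobarbital controls, 0.971 to 0.976 for Ha-ras tumours and 0.926 to 0.979 for untreated controls. miR-122, the main miRNA of hepatocytes, had a mean level of 14.09 ± 0.13 on the log2 scale (SD, n = 3) in phenobarbital controls and 14.19 ± 0.05 (n = 3) in untreated controls. miR-182 and miR-375 were detected on 0 arrays.

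The first comparison asked which miRNAs differed between Ctnnb1-mutated tumours and control liver of the same arm. miR-199a-3p, a miRNA of mesenchymal cells, was 2.24-fold lower in the tumours, with a log2 level of 5.60 ± 0.34 (SD, n = 7) against 6.76 ± 0.10 (n = 3; log2 fold change -1.16, SE 0.21, limma adjusted p = 0.00187). miR-10a, encoded within a Hox gene cluster, was 1.84-fold lower (-0.88, SE 0.15, adjusted p = 0.00158). miR-195 and miR-497, which come from 1 primary transcript and share the seed of the miR-15 family, fell by 0.78 (adjusted p = 0.00158) and 0.63 (adjusted p = 0.0178). The star strands miR-30a* and miR-30e* fell by 0.48 (adjusted p = 0.00382) and 0.40 (adjusted p = 0.00318). All 7 tumours lay below all 3 controls for miR-199a-3p, miR-10a, miR-195, miR-30a* and miR-30e*, and 6 of 7 did for miR-497. Groups of 7 and 3 part in this way, in either direction, for 1.67% of miRNAs by chance, and 14 of the 96 tested parted.

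In all, 8 of 96 miRNAs passed, 0 higher and 8 lower, and 21 had an unadjusted p under 0.05. The other pair, miR-338-3p and miR-345-5p, chosen after their values were seen, fell by 0.37 and 0.48 (both adjusted p = 0.0237). miR-30e*, miR-338-3p and miR-345-5p were at the floor on some tumour arrays, so that their falls depend in part on it. In the miR-30 family 2 of 7 tested members fell, 3 when adjusted over the list alone, and miR-30c had a log2 fold change of -0.57 (adjusted p = 0.0533). The list test gave an adjusted p of 0.0539 (with an estimated correlation, p = 0.164 and adjusted p = 0.832). The let-7 family, regulators of growth genes including Ras, had 0 of 9 members called and 4 adjusted over the list alone, with a median of -0.32 and let-7c at -0.32 (adjusted p = 0.0533; list test adjusted p = 0.156). Of the endothelial and mesenchymal list 1 of 3 was called, 2 adjusted over the list alone. miR-126-3p, of endothelium, stood at -0.28 (adjusted p = 0.154) and miR-143, of smooth muscle and stroma, at -0.31 (adjusted p = 0.272; list test adjusted p = 0.145). The medians of these 3 lists kept their sign under the other scalings. Among the hepatocyte-enriched miRNAs 0 of 9 passed, and their median of -0.11 became 0.04 with scaling over all mouse probes. miR-122 was at -0.42 (SE 0.20, adjusted p = 0.239). miR-21, a miRNA induced by Ras and AP-1 signalling, was at 0.46 (SE 0.23, adjusted p = 0.261).

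The miR-15-16 family had miR-195 and miR-497 called lower of 5 members. Its median was 0.07 while its mean was -0.19 and its test pointed down (list test adjusted p = 0.691). The miR-17-92, leukocyte, miR-29 and miR-23-27-24 lists and the Ras, MAPK and AP-1 list had 0 members called, 1 of miR-29 (lower) when adjusted over the list alone, with list test adjusted p-values from 0.243 for miR-17-92 to 0.682 for miR-23-27-24. Scaling over all mouse probes moved the median of all tested miRNAs from -0.05 to 0.10, and 0 miRNAs were called under it, although the 8 stayed below 0. The total gene signal called 3 higher and 6 lower, and the deposited values 4 higher and 2 lower. Without phenobarbital control replicate 6, 5 miRNAs were called, and without Ctnnb1 tumour replicate 1, 18. miR-497 lost its call without phenobarbital control replicate 4 (adjusted p = 0.0901) or 6 (adjusted p = 0.0831). With slide as a fixed block miR-10a was at -1.13 and miR-195 at -0.92 (both adjusted p = 0.135). The 1 call was let-7e at -2.11 (adjusted p = 0.00439), chosen after its values were seen. These estimates rest on Ha-ras tumour replicate 1, the only array of slide 1 outside the Ctnnb1 tumours. There let-7e was at 7.15, against 5.76 and 5.36 in Ha-ras tumour replicates 2 and 3.

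**Figure D1:**
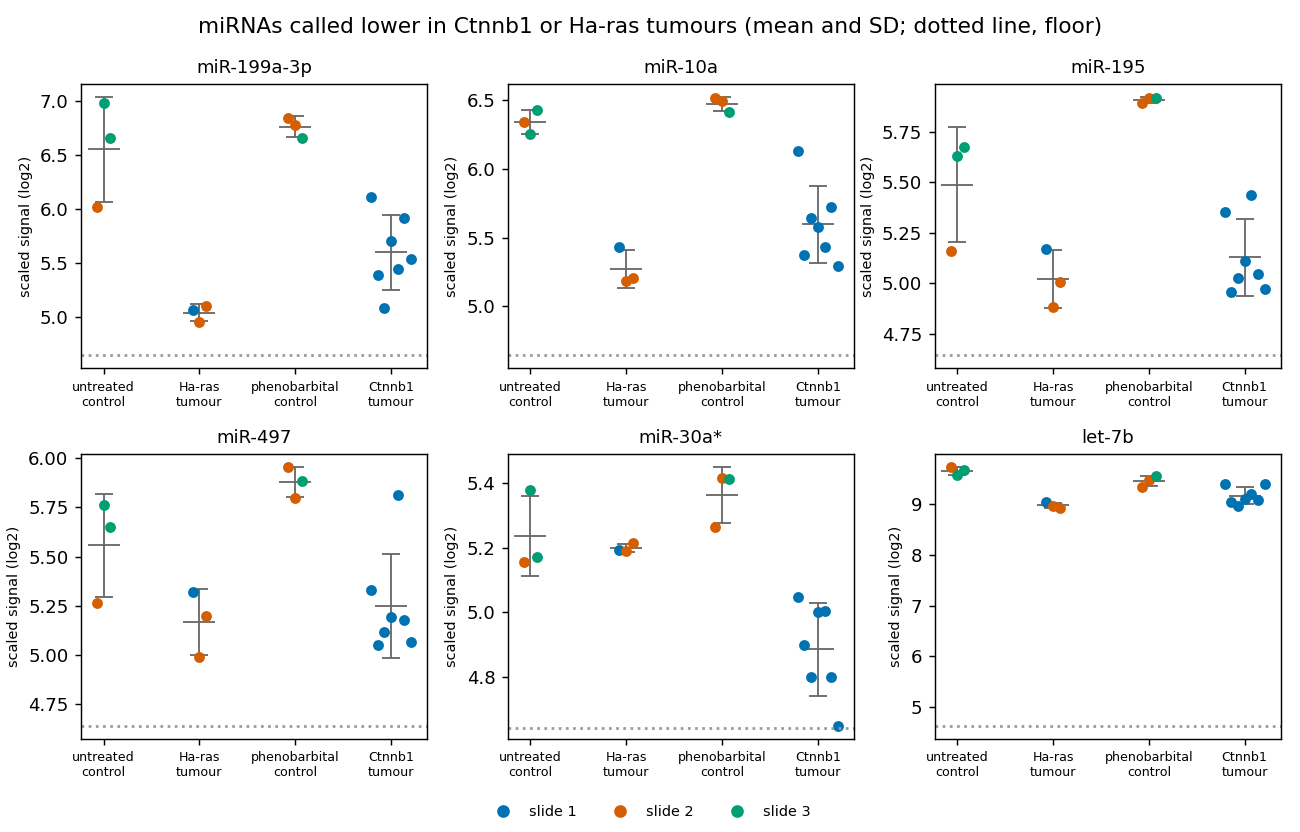
Scaled signal (log2) of miR-199a-3p, miR-10a, miR-195, miR-497, miR-30a* and let-7b on each array, by group, with points coloured by slide, bars for the mean and SD and a dotted line for the floor at 4.64. All 7 Ctnnb1 tumours lie below the 3 phenobarbital controls for miR-199a-3p, miR-10a, miR-195 and miR-30a*, and all 3 Ha-ras tumours lie below the 3 untreated controls for miR-199a-3p, miR-10a and let-7b.

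The second comparison set Ha-ras-mutated tumours against untreated controls. miR-146b, a feedback regulator of NF-kappaB signalling, was 11.8-fold higher, at 8.37 ± 0.75 (SD, n = 3) against 4.81 ± 0.17 (n = 3; log2 fold change 3.56, SE 0.24, adjusted p = 3.78e-08), and it was detected on 2 of the 3 control arrays. miR-31 rose 1.98-fold (0.99, SE 0.11, adjusted p = 1.91e-05), and it too was detected on 2 of the 3 control arrays, so that both folds depend in part on the floor. miR-21 rose 2.43-fold (1.28, SE 0.27, adjusted p = 0.00445), and miR-34a, a transcriptional target of p53, rose 3.91-fold (1.97, SE 0.48, adjusted p = 0.00845). miR-199a-3p was 2.85-fold lower (-1.51, SE 0.25) and miR-10a 2.10-fold lower (-1.07, SE 0.17; both adjusted p = 0.000509). miR-193 fell by 1.18 (adjusted p = 0.000694). All 3 tumours lay above all 3 controls for the 4 named as higher and below them for the 3 named as lower, a separation that chance gives for 10% of miRNAs in 1 direction or the other, and 41 of the 96 parted in this way.

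In all, 28 of 96 miRNAs passed, 9 higher and 19 lower, and 34 had an unadjusted p under 0.05. The Ras, MAPK and AP-1 list, of miRNAs reported downstream of Ras, had a median of 0.99 and 2 of its 3 tested members called, miR-21 and miR-31, and 3 adjusted over the list alone. miR-221, a repressor of the cell cycle inhibitor p27, was at 0.53 (adjusted p = 0.0549). The list test had an adjusted p of 0.0133 (with an estimated correlation, p = 0.00332 and adjusted p = 0.0913, which ends the call). Of the miR-23-27-24 clusters miR-23a, miR-27a and miR-24, which both clusters encode, rose by 1.04, 1.12 and 0.60 (adjusted p = 0.00821, 0.0146 and 0.0272), while miR-23b and miR-27b fell by 0.53 and 0.56 (adjusted p = 0.00821 and 0.0229; list test adjusted p = 0.568). Under scaling over all mouse probes miR-23b turned to 0.04. In the let-7 family let-7b, let-7g and let-7c fell by 0.68, 0.49 and 0.43 (adjusted p = 0.001, 0.0272 and 0.0146), and 0 of the other 6 tested members passed. Its median of -0.03 turned to 0.55 under that scaling, to 0.08 with quantile scaling and to 0.01 with scaling on the median of detected probes, as let-7g turned to 0.08 and let-7c to 0.14 under the first (list test adjusted p = 0.682). miR-130a rose by 0.69 (adjusted p = 0.00537).

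miR-96, of the miR-183 cluster, was at least 1.76-fold higher (adjusted p = 0.0374), and not well above background on any control array. By group means, miR-143 and miR-338-3p were at least 1.40-fold and 1.26-fold lower (adjusted p = 0.0146 and 0.00537), and not well above background on any tumour array. Neither was called with slide as a fixed block. The fall of miR-143 rests on untreated control replicates 2 and 3, both on slide 3, at 5.60 and 5.67. Replicate 1, on slide 2, was near the floor at 4.67. The endothelial and mesenchymal list had 2 of 3 members called lower, miR-199a-3p and miR-143 (list test adjusted p = 0.150), beside miR-126-3p at -0.30 (adjusted p = 0.141). The leukocyte list had 1 of 4 called, miR-146b. Its median was -0.17 while its mean was 0.69 and its test pointed up (adjusted p = 0.408), and miR-142-3p and miR-223, abundant in leukocytes, were at -0.45 (adjusted p = 0.425) and -0.47 (adjusted p = 0.227). In the miR-30 family miR-30b and miR-30e* fell by 0.33 and 0.26 (adjusted p = 0.0146 and 0.042; list test adjusted p = 0.450), and miR-30e* turned to 0.01 and the family's median from -0.26 to 0.08 under scaling over all mouse probes. Hepatocyte-enriched miR-378 fell by 0.41 (adjusted p = 0.0162). miR-22* was called lower too (adjusted p = 0.0146), but it was at the floor on all 3 tumour arrays, so that its size is not measured and its p rests on an SD of 0 there. The list test adjusted p was 0.568, the list's median of -0.22 turned to 0.36 under that scaling, and miR-122 was at 0.06 (SE 0.24, adjusted p = 0.910). miR-92a, of the miR-17-92 list, and miR-195, of the miR-15-16 family, fell by 0.78 and 0.47 (adjusted p = 0.0146 and 0.0366; list tests 0.931 and 0.655), and miR-195 turned to 0.02 under that scaling. miR-125b-5p and miR-365 fell by 0.44 and 1.18 (adjusted p = 0.0229 and 0.0474). In the miR-29 family 0 of 3 were called, with a median of -0.18, a mean of -0.05 and a test that pointed up (adjusted p = 0.892), and the median turned to 0.39 under that scaling. The last called, miR-139-5p, chosen after its values were seen, fell by 0.41, in part set by the floor, as is the fall of miR-30e*.

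Scaling moved this comparison. With all mouse probes the median of all tested miRNAs rose from -0.06 to 0.28 and the calls were 12 higher and 0 lower, and with quantile scaling they were 8 higher and 6 lower. With slide as a fixed block 9 miRNAs were called, among them miR-146b at 3.70 (adjusted p = 8.8e-06) and miR-31 at 0.87 (adjusted p = 0.00481), whereas miR-34a was at 1.36 (adjusted p = 0.230). Within slide 2, with 2 Ha-ras tumours against 1 untreated control assumed to vary like the other groups, the 5 called were miR-146b (3.78), miR-31 (0.89), miR-21 (1.68), miR-10a (-1.15) and let-7b (-0.79). Leaving out untreated control replicate 2 or Ha-ras tumour replicate 1 left 13 miRNAs called, and leaving out untreated control replicate 3 left 18. miR-146b, miR-31, miR-21, miR-23a, miR-130a, miR-199a-3p, miR-10a, miR-193, let-7b and miR-338-3p passed with each of the 16 arrays left out. The calls of miR-34a and miR-23b ended without untreated control replicate 2 (both adjusted p = 0.0502) and that of let-7c without replicate 3 (adjusted p = 0.0511). That of miR-27a ended without untreated control replicate 1 (adjusted p = 0.0592) or Ha-ras tumour replicate 1 (adjusted p = 0.0558). Those of let-7g, miR-24, miR-27b, miR-92a, miR-195, miR-125b-5p, miR-143, miR-378, miR-30b, miR-22*, miR-96, miR-30e* and miR-365 ended when any 1 of at least 2 different arrays was left out, with highest adjusted p-values from 0.0632 for miR-30b to 0.158 for miR-30e*.

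**Figure D2:**
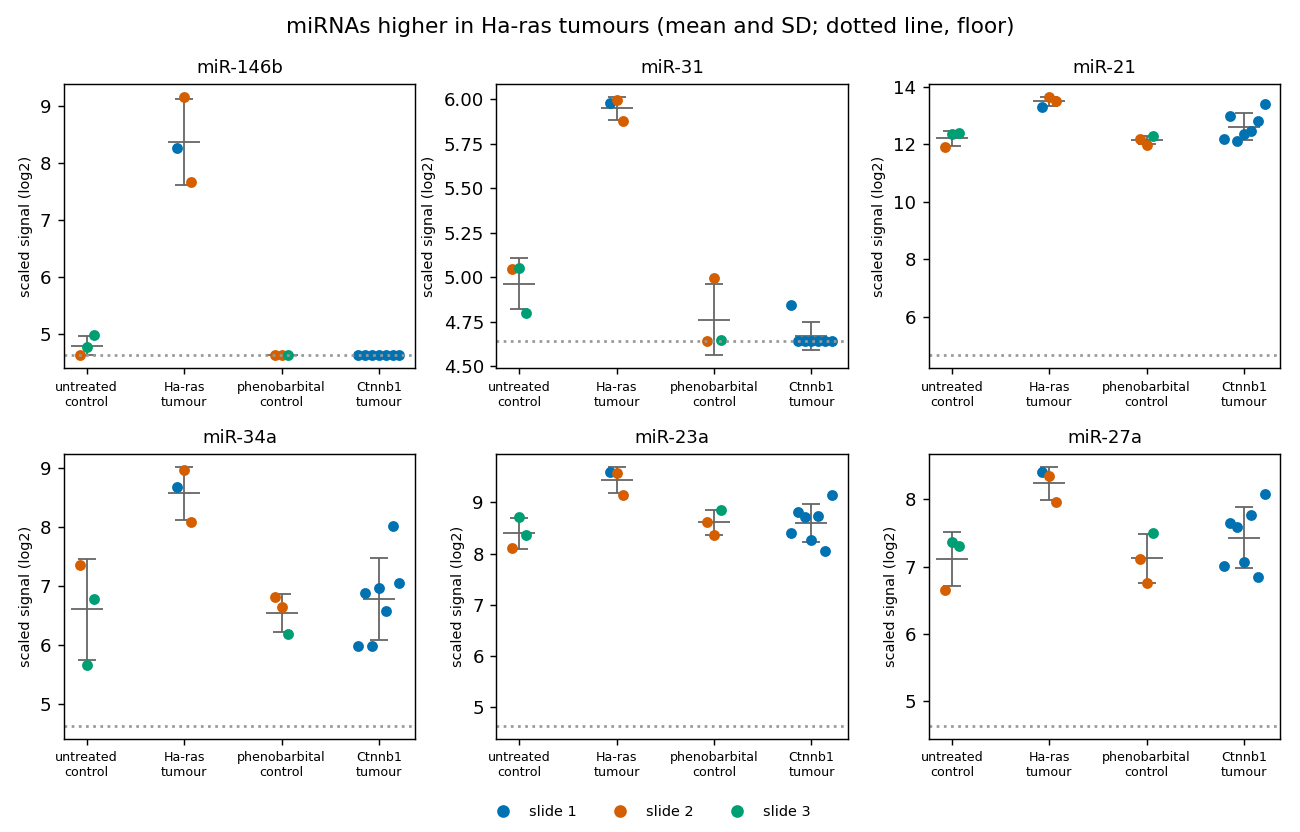
Scaled signal (log2) of miR-146b, miR-31, miR-21, miR-34a, miR-23a and miR-27a on each array, by group, with points coloured by slide, bars for the mean and SD and a dotted line for the floor at 4.64. All 3 Ha-ras tumours lie above the 3 untreated controls in each panel, and miR-146b is at the floor on all 7 Ctnnb1 tumour arrays.

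The third comparison set the 2 tumour kinds against each other, where genotype and phenobarbital differ together and carcinogen dose and age may differ too. Ha-ras tumours held at least 11.9-fold more miR-146b (adjusted p = 1.94e-09), which was not well above background on any of the 7 Ctnnb1 tumour arrays. Its values at the floor there lower this p. miR-31 was 2.43-fold lower in Ctnnb1 tumours (-1.28, SE 0.10, adjusted p = 7e-08), where it was detected on 1 of 7 arrays, so that this fold depends on the floor. miR-34a was 3.47-fold lower (-1.79, SE 0.41, adjusted p = 0.00897) and miR-21 1.84-fold lower (-0.88, SE 0.23, adjusted p = 0.0179). miR-709 was 2.02-fold higher (1.02, SE 0.17, adjusted p = 0.000902) and miR-15a 1.60-fold higher (0.68, SE 0.13, adjusted p = 0.00164). miR-122 was lower by a log2 fold change of -0.59 (adjusted p = 0.0407), with 13.67 ± 0.40 (SD, n = 7) in Ctnnb1 and 14.26 ± 0.26 (n = 3) in Ha-ras tumours. All 7 Ctnnb1 tumours lay below the 3 Ha-ras tumours for miR-146b, miR-31 and miR-34a and above them for miR-709 and miR-15a, and 18 of the 96 tested parted, against 1.67% by chance.

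In all, 29 of 96 miRNAs passed, 16 higher and 13 lower in Ctnnb1 tumours, and 37 had an unadjusted p under 0.05. The Ras, MAPK and AP-1 list had 3 of 3 members lower, miR-221 with -0.50 (adjusted p = 0.038), and a list test adjusted p of 0.0133 (with an estimated correlation, p = 0.00322 and adjusted p = 0.0913, which ends the call). miR-23a and miR-27a were at -0.84 and -0.81 (adjusted p = 0.0134 and 0.0315) and miR-23b and miR-27b at 0.38 and 0.52 (adjusted p = 0.0207 and 0.0188; list test adjusted p = 0.682), and miR-23b turned to -0.17 under scaling over all mouse probes. Of the miR-30 family miR-30a, miR-30c and miR-30a* were lower by log2 fold changes of -0.77, -0.59 and -0.31 (adjusted p = 0.0217, 0.0226 and 0.0281; list test adjusted p = 0.407). Of the miR-17-92 list, a cluster that promotes proliferation, miR-92a, miR-19a and miR-19b were higher by 0.75, 0.61 and 0.62 (adjusted p = 0.00982, 0.0357 and 0.038; list test adjusted p = 0.407), with a median of 0.26 that turned to -0.16 with all probes and to -0.03 with quantile scaling. Of the miR-15-16 family miR-15a and miR-16 were higher, miR-16 by 0.52 (adjusted p = 0.0284; list test adjusted p = 0.266), while miR-16 turned to -0.03 and the family's median from 0.37 to -0.18 under scaling over all mouse probes. The hepatocyte-enriched list had miR-22 higher by 0.55 (adjusted p = 0.0281), miR-22* called higher against Ha-ras arrays all at the floor (adjusted p = 0.0134), and miR-101b and miR-122 lower, miR-101b by -0.63 (adjusted p = 0.0186; list test adjusted p = 0.717). In the leukocyte list miR-223 was higher by 0.82 (adjusted p = 0.0188) and miR-146b lower, and its median of 0.29 opposed its mean of -0.58 and its test (adjusted p = 0.682). The let-7, miR-29 and endothelial and mesenchymal lists had 0 members called (list test adjusted p = 0.682, 0.802 and 0.655).

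With scaling over all mouse probes the median of all tested miRNAs fell from 0.08 to -0.32 and the calls were 2 higher and 20 lower. With the median of detected probes it rose to 0.13 and they were 22 higher and 10 lower, and quantile scaling gave a median of -0.11. Within slide 1, with 1 Ha-ras tumour assumed to vary like the Ctnnb1 tumours, 6 were called, among them miR-146b (-3.62), miR-31 (-1.31) and miR-15a (0.92). With slide as a fixed block 8 were called, among them miR-709 at 1.04 (adjusted p = 0.0428). The calls of miR-34a, miR-21, miR-122, miR-23a, miR-27a and the miR-30 family ended under it. Without Ha-ras tumour replicate 2, 5 miRNAs were called, and without replicate 1, 11. miR-146b, miR-31, miR-15a and miR-709 passed with each of the 16 arrays left out. Without Ha-ras tumour replicate 2 the calls of miR-34a (adjusted p = 0.0663), miR-21 (adjusted p = 0.0837), miR-22* (adjusted p = 0.0663) and miR-101b (adjusted p = 0.107) ended. Those of the other miRNAs named for this comparison ended when any 1 of at least 2 different arrays was left out, Ha-ras tumour replicate 2 among them, with highest adjusted p-values from 0.0658 for miR-92a to 0.207 for miR-16.

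The Dlk1-Dio3 imprinted locus carries a large cluster of miRNAs expressed from the maternal chromosome. All 73 of its miRNAs on the array lay between Dlk1 and Dio3 in the gene table, and 7 were tested. Ctnnb1 tumours had 8 to 23 list members detected per array, phenobarbital controls 9, 2 and 15, and each of the 6 arrays of the arm without phenobarbital 1, miR-494. The count of detected members and its permutation tests were chosen after the values were seen. With the arm permuted within tumours and within controls, the difference of the means was 11.6 members. It had an exact two-sided p of 0.000417, the smallest that 2400 permutations give. Within slides it had an exact two-sided p of 0.00417, the smallest of 240. miR-379 was detected on 7 of 7 Ctnnb1 tumours, 2 of 3 phenobarbital controls and 0 of the other 6 arrays.

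Apart from miR-136 and miR-494, the tested members were detected on every array of a group only in the Ctnnb1 tumours. They were thus tested through that group, which favours values above 0, and the list tests, where it comes first in a comparison. Against Ha-ras tumours 5 of the 7 tested members were called higher in Ctnnb1 tumours and 6 adjusted over the list alone. miR-379 was at least 2.67-fold higher (adjusted p = 0.0186), miR-136 at least 2.06-fold (adjusted p = 0.0281), miR-299* at least 1.88-fold (adjusted p = 0.0357), miR-127 at least 1.55-fold (adjusted p = 0.0365) and miR-377 at least 1.41-fold (adjusted p = 0.0456). The fitted median was 0.93, or 0.74 with 6 members at their bound (list test adjusted p = 0.0796; p = 0.229 with an estimated correlation). Each of the 5 lost its call without Ha-ras tumour replicate 2, miR-379 with an adjusted p of 0.0837 and miR-377 of 0.124. Each also lost its call with slide as a fixed block. Between phenobarbital and untreated controls 6 of the 7 lay above 0 with 0 called. The fitted median was 0.64, or 0.52 with 6 members at their bound, and the mean 0.28 (list test adjusted p = 0.158). miR-494 was the exception, at -2.35, and untreated control replicate 3, the array farthest from its group's mean, held a high miR-494 level of 12.29. That level makes up most of the array's distance. Between Ctnnb1 tumours and phenobarbital controls the 7 members lay above 0 with 0 called, with a median of 0.29 (list test adjusted p = 0.0796) and miR-379 at 0.61 (SE 0.44, adjusted p = 0.430). The list passed without Ctnnb1 tumour replicate 1 (adjusted p = 0.0459) or 6 (adjusted p = 0.0152) or phenobarbital control replicate 6 (adjusted p = 0.00883), each with the preset correlation (with an estimated one, p = 0.189, 0.119 and 0.1). Between Ha-ras tumours and untreated controls 6 of the 7 were not well above background in either group, so that the median of 0 carries no fold (list test adjusted p = 0.866), and miR-494 was at -1.80 (SE 1.22, adjusted p = 0.326). Without phenobarbital control replicate 5, which held 2 list members, the median between the controls was 0.96 (list test adjusted p = 0.00725; with an estimated correlation, p = 0.0994).

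**Figure D3:**
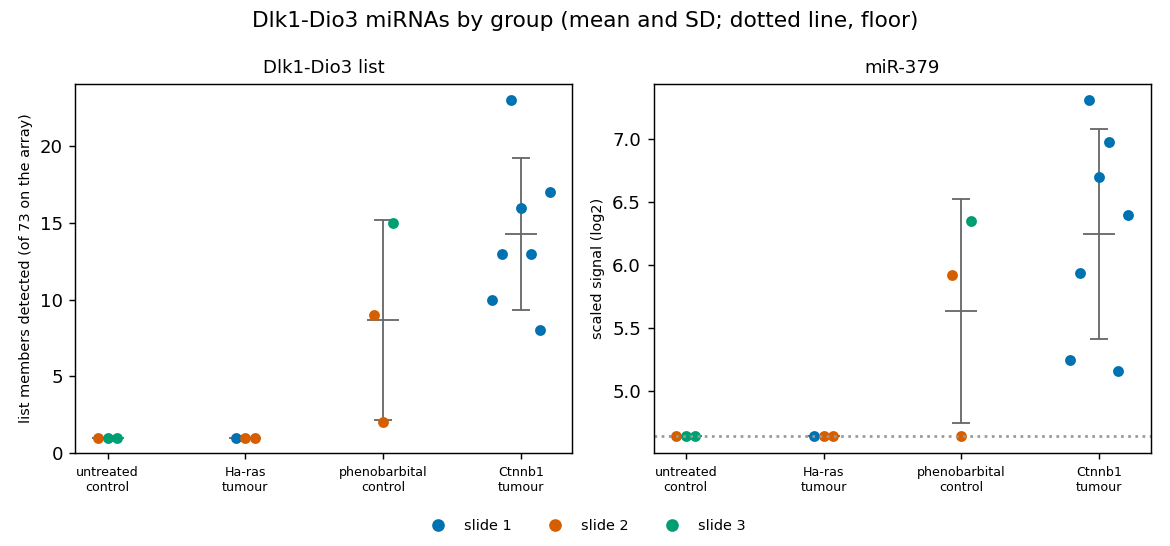
Left, number of Dlk1-Dio3 list members detected on each array, of 73 on the array; right, scaled signal (log2) of miR-379, by group, with points coloured by slide, bars for the mean and SD and a dotted line for the floor at 4.64. The 6 arrays of the arm without phenobarbital have 1 member detected and miR-379 at the floor, and the 7 Ctnnb1 tumours have 8 to 23.

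Phenobarbital controls were set against untreated controls to compare the arms in liver without tumour. The labels part them by phenobarbital, and carcinogen exposure, dose and age may differ too. limma called 0 of 96 miRNAs, with 6 at an unadjusted p under 0.05 and a smallest adjusted p of 0.559. The 3 with the smallest p were miR-29b at 0.41 (SE 0.14), miR-195 at 0.42 (SE 0.16) and miR-130a at 0.37 (SE 0.15, all adjusted p = 0.559). Each was higher on 3 of 3 phenobarbital arrays, as their choice by p makes likely. Chance parts groups of 3 and 3 for 10% of miRNAs in 1 direction or the other. Here 14 of 96 parted above and 10 below. The 5 members of the miR-15-16 family lay above 0, with a median of 0.32 (list test adjusted p = 0.0539, and 0.741 with an estimated correlation). The 3 of the miR-29 family did too, with a median of 0.24 and 1 member called adjusted over the list alone (list test adjusted p = 0.150). Among the other 8 lists besides Dlk1-Dio3, list test adjusted p-values ran from 0.158 for the hepatocyte-enriched to 0.968 for the leukocyte list, and for let-7 and for the endothelial and mesenchymal list the test pointed down while median and mean were above 0. Quantile scaling, without the floor, called 6 miRNAs, the deposited values 5 and the total gene signal 4, and 1 was called without untreated control replicate 1.

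The difference of the tumour effects, each tumour against its own control, passed for 2 of 96 miRNAs, and 17 had an unadjusted p under 0.05. miR-146b had a difference of -3.56 (SE 0.32, adjusted p = 1.44e-06) and miR-31 of -1.08 (SE 0.15, adjusted p = 0.000168), Ctnnb1 effect minus Ha-ras effect. miR-146b was not well above background on any array of the phenobarbital arm, so that its difference equals the Ha-ras effect with its sign turned, and its values at the floor lower its SE. miR-31 was detected on 1 of 7 Ctnnb1 tumours and 1 of 3 phenobarbital controls, so that its difference depends on the floor. For miR-21 and miR-34a, called in Ha-ras tumours and not in Ctnnb1 tumours, a difference between the effects was not shown (-0.82, adjusted p = 0.230, and -1.74, adjusted p = 0.164). The smallest list test adjusted p was 0.0539, for the Ras, MAPK and AP-1 list (with an estimated correlation, p = 0.0108 and adjusted p = 0.199). The tumour comparisons share no control arrays. Their called miRNAs had 5 in common among 8 and 19 lower (miR-10a, miR-195, miR-199a-3p, miR-30e* and miR-338-3p), where independent draws give 1.58. The 2 comparisons are not independent, since they share 1 fitted spread per miRNA. In both, no control was on slide 1 and no tumour on slide 3, so a slide difference could enter both. Among those higher no overlap was possible, with 0 called in Ctnnb1 and 9 in Ha-ras tumours.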

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

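The tests of slides, leukocyte RNA, cross-hybridisation, scaling, cell loss, brightness and phenobarbital below were chosen only after the results were seen; the splits of the samples, the distance of single arrays and the differences of tumour effects were planned.

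miR-146b and miR-31 differed between the tumour effects, by a test of the difference itself: -3.56 and -1.08, Ctnnb1 minus Ha-ras. miR-146b was at the floor on all 10 arrays of the phenobarbital arm and miR-31 on 6 of 7 Ctnnb1 tumours, so that the first value is the Ha-ras effect with its sign turned and the second depends on the floor. In the group of 7 Ctnnb1 tumours, 5 of 68 named values tested had 1 array far from the others (a large gap to the nearest array as a share of the range, by Dixon's test), where chance gives about 1 in 20. In Ctnnb1 tumour replicate 5, miR-497 lay above the next array at 5.81 against 5.33 (share 0.636) and miR-22 at 12.38 against 11.81 (share 0.664). In that array let-7a lay below the next at 9.50 against 10.12 (share 0.627) and miR-365 at 5.37 against 6.76 (share 0.608). miR-31 lay above the floor in Ctnnb1 tumour replicate 1, at 4.84 against 4.64 on the other 6 arrays; its share of 1 follows from the floor and says nothing of that array.

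The same arrays were split at random into groups of the same sizes and tested again. For the 8 calls in Ctnnb1 tumours against their controls, 2 of 100 splits called as many, the real split among them. The highest other count was also 8. Between the tumours, with 29 calls, 1 of 100 splits, the real split, called as many and the highest other count was 6. Random regrouping thus seldom gave as many calls in either comparison. In the first, no slide held both groups, so the splits cannot part a group difference from a slide difference. For Ha-ras tumours against their controls (28 calls, 1 of 10 splits as high, highest other 2) and for the controls (0 calls, 10 of 10, highest other 1) there are too few splits for a share under 0.05. For the difference of the tumour effects chance is not excluded, since 14 of 100 splits called 2 or more and the highest other count was 23; these splits put tumours among controls of the same arm, so that this structure of the samples enters the counts.

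miR-146b and miR-31 were higher in Ha-ras tumours than in untreated controls. A difference between slides is argued against, as with slide as a fixed block over all 16 arrays the lower 95% limit was 2.95 for miR-146b and 0.533 for miR-31. More leukocyte RNA is argued against for miR-146b, since the upper 95% limits of miR-142-3p and miR-223 were 0.376 and 0.104, below its lower limit of 3.04; miR-31 is not in the leukocyte list, and this does not bear on it. Binding of the related miR-146a to the probes of miR-146b is argued against, with an upper limit for miR-146a of 0.554. The limits of miR-146b rest on a spread fitted over all 16 arrays, with those of the phenobarbital arm at the floor. They are narrower than the Ha-ras tumours and untreated controls alone would give. A candidate explanation left open is expression driven by the Ha-ras mutation, while the Ctnnb1 tumours, all given phenobarbital, had miR-146b at the floor on all 7 arrays and miR-31 on 6.

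The miRNAs called in Ctnnb1 tumours were all lower than in phenobarbital controls. Scaling over all mouse probes called 0 of the 8. Their median was -0.40 (median SE 0.24) under it against -0.56 (median SE 0.13), with a highest upper 95% limit of 0.145. Relative to the median of all tested miRNAs their median was -0.51 under both, and the 8 lay below 0 under each of the 4 scalings. That scaling uses a percentile among undetected probes. Quantile scaling, which also drops the floor, called 5 of the 8 and scaling on the median of detected probes 4, so the scaling stays open. A loss of endothelial and mesenchymal cells cannot be told apart, since of the 8 only 1, miR-199a-3p, itself a mesenchymal miRNA, fell beyond the 95% limits of miR-126-3p and miR-143. A difference between slides cannot be told apart either, as no slide held both groups and with slide as a block the highest upper limit among the 8 was 0.140, and the Ctnnb1 mutation stays open, untested.

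More Dlk1-Dio3 miRNAs were detected in the phenobarbital arm than in the other arm. A difference between slides is argued against by the arm permuted within slides (exact two-sided p = 0.00417, the smallest of 240). Brighter arrays are argued against too: the other miRNAs detected differed by -1.53 between the arms (exact permutation p = 0.754), while list members per other miRNA detected differed with an exact permutation p of 0.00417. Phenobarbital alone cannot be told apart from the Ctnnb1 tumours' part in it, because the controls gave an exact p of 0.1, the smallest that 3 against 3 arrays can give. A candidate explanation is that phenobarbital raises the cluster in liver and in tumour alike, and among the tumours treatment and mutation were not separable. Carcinogen dose and age, not settled per sample, may also differ between the arms.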

How the results depend on the processing

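Of 156 values of named miRNAs, 5425 comparisons with alternatives gave 4811 on the same side of the threshold (167 of them, not called, with the other sign), 506 that lost the threshold, 31 (an array left out) and 70 (other alternatives) that gained it, and 7 called values with the other sign. miR-146b kept its call between the tumours under all alternatives that gave a value. The alternatives with a floor 4 times lower, without the 2 arrays farthest from their groups and with 5 miRNAs left out were chosen after seeing the data. The Dlk1-Dio3 list's adjusted p (with the preset correlation) ran from 2.8e-05 to 0.521 in Ctnnb1 tumours, from 0.00106 to 0.977 in Ha-ras tumours and from 1.11e-12 to 0.944 between the controls. The 0.00106 in Ha-ras tumours is from the replicate block with slide. The list members other than miR-494 were at the floor on all arrays of that arm, so this value rests on no measured fold. Where no cause is given, the cause was not tested. The arrays' signal over background limits the rest: 96 of 566 miRNAs were testable.

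Scaling: with quantile scaling, calls were 14 for Ha-ras tumours against control, 6 between the controls and 1 for the difference of effects, and the Dlk1-Dio3 median between the controls was 3.33 (adjusted p = 4.12e-07; with an estimated correlation, p = 0.00804). Quantile scaling dropped the floor as well. On the untreated controls 6 of the 7 tested members were not well above background, so that the size of the 3.33 is not measured. With all mouse probes, calls were 0 for Ctnnb1 and 12 for Ha-ras tumours against control, and the Dlk1-Dio3 medians were 0.50 (adjusted p = 0.0276; with an estimated correlation, p = 0.179) in Ctnnb1 tumours and 0.36 (adjusted p = 0.0239; with an estimated correlation, p = 0.152) between the controls. There the sign turned in Ha-ras tumours for miR-23b (0.0445), let-7g (0.0780), miR-195 (0.0235), let-7c (0.139) and miR-30e* (0.00718), and between the tumours for miR-16 (-0.0329) and miR-23b (-0.169); this scaling moves all values of an array together. With the median of detected probes, 4 were called for Ctnnb1 tumours.

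Signal: with normexp background, calls were 4, 18 and 15 for the 3 comparisons with tumours (Ctnnb1, Ha-ras, between them) and 1 for the difference. The total gene signal gave 4 between the controls and Dlk1-Dio3 medians of 0.84 (adjusted p = 0.0249; with an estimated correlation, p = 0.283) in Ctnnb1 tumours and 1.81 (adjusted p = 3.21e-11; with an estimated correlation, p = 0.0157) between the controls. The deposited values, whose handling of low signals is unknown, gave 12 for Ha-ras tumours, 5 between the controls and 0 for the difference, and Dlk1-Dio3 medians of 1.54 (adjusted p = 0.00119; with an estimated correlation, p = 0.198) and 4.13 (adjusted p = 1.11e-12; with an estimated correlation, p = 0.0161). A floor 4 times higher gave 3 for Ctnnb1 tumours and 17 between the tumours; 4 times lower, a Dlk1-Dio3 median of 2.11 (adjusted p = 0.000768; with an estimated correlation, p = 0.0495) between the controls. The brightest probe gave 4 for the difference.

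Tests: with no filter the Dlk1-Dio3 medians were 0.20 (adjusted p = 0.023; with an estimated correlation, p = 0.352) in Ctnnb1 tumours and 0.27 (adjusted p = 0.0482; with an estimated correlation, p = 0.408) between the controls. With only miRNAs detected on all arrays, which tests fewer, calls were 4 for Ctnnb1 tumours, 19 between the tumours and 0 for the difference, and the Dlk1-Dio3 list could not be tested. Only the 2 groups compared, with fewer samples, gave 13 between the tumours. Array weights gave 23 for Ctnnb1 tumours and 7 for the difference. A 2-fold threshold as well left 1, 9 and 7. With 5 miRNAs left out the Dlk1-Dio3 median between the controls was 0.67 (adjusted p = 0.0382; with an estimated correlation, p = 0.180).

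Slide: as a fixed block, calls were 1, 9 and 8 for the comparisons with tumours; as a random block, with a consensus correlation of -0.12, 20 for Ctnnb1 tumours and 4 for the difference. Within slide 1, 6 were called between the tumours; within slide 2, 5 for Ha-ras tumours; within slide 3, 1 between the controls (1 array, assumed to vary like the other groups, against 2), with a Dlk1-Dio3 median of 1.22 (adjusted p = 0.00886; with an estimated correlation, p = 0.0944). No slide allowed this for Ctnnb1 tumours against control. The replicate block, which takes equal numbers as pairs, gave 2 for Ctnnb1 and 14 for Ha-ras tumours; with slide, 0 and 0, and Dlk1-Dio3 medians of 2.49 (adjusted p = 2.8e-05; with an estimated correlation, p = 0.0713) and 1.66 (adjusted p = 0.00106; with an estimated correlation, p = 0.105). The 1.66, for Ha-ras tumours, carries no measured fold. There 6 of the 7 members were at the floor on all arrays of that arm, so it comes from slide terms fitted on the other arm. Correlations of equal numbers from -0.77 to 0.58 give no sign of pairs.

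Leaving out each array gave 5 (phenobarbital control replicate 6) to 18 calls (Ctnnb1 tumour replicate 1) for Ctnnb1 tumours and a Dlk1-Dio3 median from 0.00866 to 0.606. It gave 13 to 33 for Ha-ras tumours (Dlk1-Dio3 0 to 0) and 5 to 29 between the tumours (5 without Ha-ras tumour replicate 2). It gave 0 to 1 between the controls (Dlk1-Dio3 0.33 to 0.96, the last without phenobarbital control replicate 5) and 2 to 3 for the difference. Without the 2 farthest arrays, untreated control replicate 3 (mostly through miR-494) and Ctnnb1 tumour replicate 5, the 5 counts were 12, 24, 30, 0 and 3.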

Other observations

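The lists of this part were fixed beforehand, and miR-494 in single arrays was looked at only after its values were seen. The erythroid miR-451 and miR-144, of red blood cells in the tissue, were at -0.41 (adjusted p = 0.604) and -0.25 (adjusted p = 0.767) in Ctnnb1 tumours and at 0.25 (adjusted p = 0.743) and 0.33 (adjusted p = 0.670) in Ha-ras tumours. Of the list of miR-99, miR-100, miR-125 and miR-181, miR-125b-5p fell in Ha-ras tumours as given above, and miR-99a was at -0.18 (adjusted p = 0.425). The miR-200 family of epithelial cells, the muscle list, the Sfmbt2 intron cluster, the X-linked testis clusters, the Igf2-H19 locus and the list of miR-224, miR-452 and other liver tumour miRNAs had 0 members tested. Herpesvirus probes, used in no comparison, were detected in 4 cases among 40 probes on 16 arrays.

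In untreated control replicate 3 miR-494 stood at 12.29, against 6.91 and 6.13 in replicates 1 and 2. The root mean square deviation of this array from its group's mean was 0.479, followed by Ctnnb1 tumour replicate 5 with 0.432. miR-494 itself makes up most of the 0.479, so that this distance says little of the array's other miRNAs. Groups of 3 were not tested for arrays far from the others.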
